A study of Mus musculus with 6 samples.

How the data were processed

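Nuclear RNA was measured in 6 libraries of mouse embryonic stem cells that carry a doxycycline-inducible, epitope-tagged AGO2. The libraries form 3 groups of 2, which received a non-targeting shRNA, an shRNA against Cnot1 or an shRNA against Cnot7. Per the labels' protocols, cells were infected with lentivirus and selected with puromycin, and directional libraries were made from ribosomal-RNA-depleted RNA of the nuclear fraction. The submitters' processing notes name bcl2fastq 2.17.1, TopHat and the genome build mm10. The program that produced the gene values is not given in the sources used here, nor is the gene annotation.

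Each of the 2 deposited tables holds 1 comparison of an shRNA group with the non-targeting group. The authors deposited 1 RPKM value (reads scaled to gene length and library size) per gene and group, so no value per library, SD or n could be computed. The deposited log2 fold change was the log2 ratio of the shRNA column to the non-targeting column within 0.001 for 16557 of 16558 and for 16114 of 16114 genes with a finite ratio. The authors also deposited a test statistic, here treated as a score, and a p-value that cannot fall below 5e-05. Their q-value matched a Benjamini-Hochberg adjustment over the genes they marked as tested. In the Cnot7 table the header of the shRNA column names Cnot1, while the fold-change header names Cnot7 and its values follow that column. The column was therefore read as Cnot7 shRNA, and every Cnot7 value rests on that reading. The non-targeting RPKM of the tables differed by a near-constant factor (median ratio 0.977, from 0.9766 at the 1st to 0.9774 at the 99th percentile), so each table was scaled separately and folds were taken within a table. Spreadsheet conversion had turned 27 gene symbols in each table into dates, and those rows could not be named.

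A gene was called when the authors' q-value was below 0.05. The log2 fold changes printed here were computed from the RPKM columns without a pseudocount, and a gene listed at 0 in a group was given no fold, counting as the lowest or highest value in a list's median. The standard error printed with a fold is the log2 fold change divided by the authors' test statistic. This implied error depends on the authors' variance model. The deposited p was smaller than a normal p from the same statistic, and the z it corresponds to was 1.55 times the statistic at the median under Cnot1 shRNA and 1.42 times under Cnot7 shRNA.

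Absolute depth is unknown. Among genes with few reads the ratio of RPKM values repeats, because 1 read in each group gives the same ratio for every gene. The 4 commonest ratios put the Cnot1 shRNA group at about 1.53 times the depth of the non-targeting group (1.39 to 1.63) and the Cnot7 shRNA group at about 0.787 times (0.733 to 0.846). These values are estimates of relative depth only.

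Gene groups came from 28 lists fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. For a list with at least 5 tested members, the median log2 fold change was ranked among 10000 random lists of the same size matched on mean RPKM in 20 bins. The resulting two-sided p, which cannot fall below 0.0002, was adjusted by Benjamini-Hochberg over the lists of a comparison. Called members per direction were also compared with those of all tested genes by a two-sided Fisher's exact test, adjusted the same way and printed where its verdict differed from that of the median. These p-values run across genes, which are not independent replicates, and members of a list are often regulated together. A change of a list between the shRNAs was tested the same way on the per-gene difference of the 2 log2 fold changes. Single genes were tested for that difference with a two-sided z from the implied errors, treating the shared controls as independent. Seed sites were searched in the longest annotated 3′ UTR of each gene in GENCODE M21, which uses the GRCm38 assembly on which mm10 is based, and 96.2% of the tested symbols were found in that annotation. The site label was permuted 100000 times within bins of expression and UTR length, and the p-values were adjusted over all families and both comparisons. The correlation of the folds was set beside simulated unchanged groups that share the controls, with 0.5 of the smaller error variance given to the controls, and with all of it. Added after the results were seen, lists as long as the called ones were taken from these groups by z, and their overlap and same-sign share were counted.

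The text names the CCR4-NOT subunits and the 8 called genes with the largest rise and the 8 with the largest fall at 1 RPKM or above. From each list it names up to 4 called members with the largest change, or the 2 most highly expressed members where none was called, plus a few Argonaute-pathway and pluripotency genes. Some genes that this rule takes are not reported here. Other genes are named only where that is said. Zscan4 genes are near-identical copies whose reads could be split among them, and their single values are uncertain.

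The tests were first run on simulated data with the real genes and implied errors. Of 11679 genes, 100 were given a log2 difference of 1 between the shRNAs and 100 a difference of 2. The difference test recovered 13% and 83% of them and called 0 unchanged genes. Lists of 20 genes raised by 0.4 were found in 100 of 100 runs for either comparison, and unchanged lists in 4 and 5 of 100. Seed-site sets raised by 0.1 were found in 40 of 40 runs and unchanged sets in 1 of 40. Genes were drawn independently in these simulations, so the rates leave out genes that are regulated together. Alternatives covered the RPKM filter, the thresholds, the adjustment, centring, pseudocounts, list matching and site type. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.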

Results

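Nuclear RNA was compared between mouse embryonic stem cells given an shRNA against Cnot1 or Cnot7 and cells given a non-targeting shRNA. CNOT1 is the scaffold of the CCR4-NOT complex, which shortens poly(A) tails and is recruited by Argonaute and TNRC6 proteins, and CNOT7 is one of its catalytic subunits. The series concerns microRNA silencing in the nucleus, and these libraries ask what happens to nuclear RNA when the deadenylase complex is targeted. Each of the 3 groups had 2 libraries. The deposited tables hold 1 RPKM value per group, so errors are those implied by the authors' test. Nothing in the labels says that the libraries came from separate cultures, and the p-values then measure a spread that may be technical. The Cnot1 shRNA libraries were deeper than the controls and the Cnot7 shRNA libraries shallower, at about 1.53 and 0.787 times the control depth.

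The targeted genes lay lower under their own shRNA, by modest amounts. Cnot1 (mm10, chromosome 8, 95719451 to 95807464, minus strand) fell from 127.5 to 91.0 RPKM under Cnot1 shRNA, a log2 fold change of -0.49 ± 0.19 (implied SE) with an adjusted p of 0.00179 in the authors' deposited table. Cnot7 (chromosome 8, 40492540 to 40515847, minus strand) read 49.1 RPKM in controls and 37.2 under Cnot7 shRNA. That change of -0.40 ± 0.39 was not called, with an adjusted p of 0.369 in the authors' deposited table. Under the other shRNA, Cnot7 read 50.2 and 50.1 RPKM (adjusted p 0.995) and Cnot1 124.6 and 107.2 RPKM (adjusted p 0.410), again in the authors' deposited table. The remaining subunits were mostly uncalled. Under Cnot7 shRNA the untargeted Cnot11 and Cnot3 had log2 fold changes of -0.46 and -0.43, and Cnot10 and Cnot8 0.24 and 0.21, none called. The fall of Cnot7 under its own shRNA therefore did not stand out from the other subunits. Cnot6l, a further deadenylase subunit, rose by 0.46 and 0.48 on the log2 scale under Cnot1 and Cnot7 shRNA, and Tnks1bp1, a protein bound to the complex, rose by 0.62 and 0.58.

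**Figure D1:**
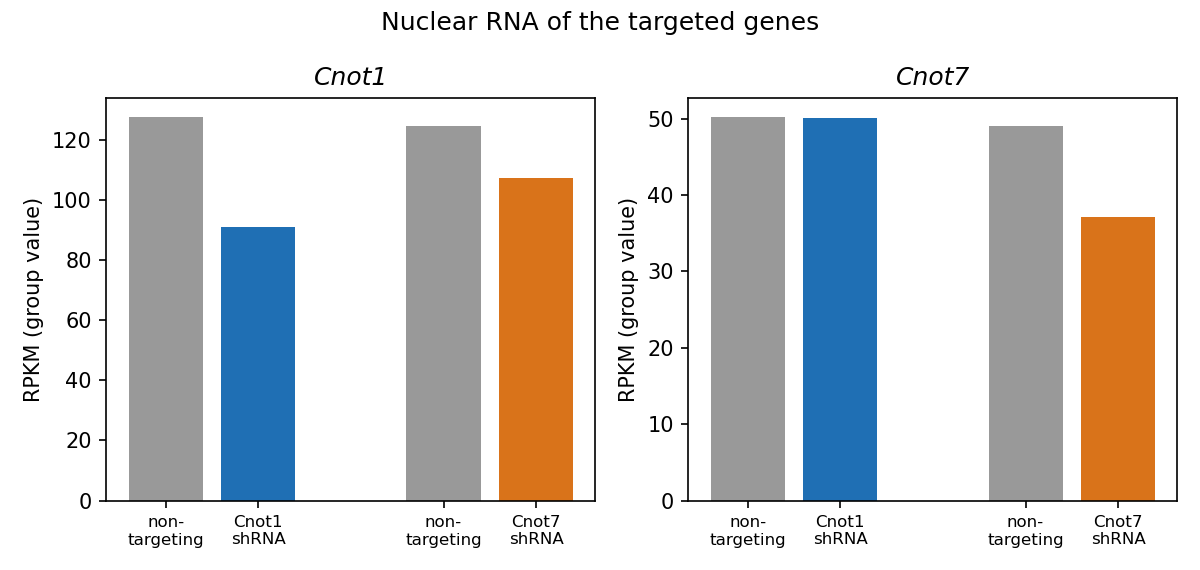
Bars show the deposited RPKM of Cnot1 (left) and Cnot7 (right) in the non-targeting group (grey) and in the shRNA group of the same table (blue for Cnot1 shRNA, orange for Cnot7 shRNA), 1 group value per bar and no error. Cnot1 stood at 91.0 RPKM under its own shRNA against 127.5 in controls, and Cnot7 at 37.2 against 49.1.

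Cnot1 shRNA was compared with the non-targeting shRNA to find the nuclear RNAs that depend on the scaffold. Genes of lipid synthesis rose, and genes of the 2-cell-like state, p53 targets and imprinted genes fell. Large rises were those of Qprt (0.580 to 4.35 RPKM, log2 fold change 2.91 ± 0.85), Chit1 (2.79), B4galnt2 (2.74), Tmem211 (2.55), Tlcd2 (2.45), the complement gene C2 (2.44) and Entpd2 (2.43). The largest falls were Nipal4 (2.03 to 0.182 RPKM, log2 fold change -3.48 ± 0.86), the transcription factor Ets1 (-3.18), Zscan4c (-2.90), Dusp13 (-2.78), Magel2 (-2.75), the ephrin ligand Efnb2 (-2.57), the endothelin gene Edn1 (-2.55) and Tdpoz4 (-2.51). The rise of Chit1 had an implied SE of 1.54, so its size is uncertain. Of 12182 tested genes, 2566 (21.1%) were called, 1542 higher and 1024 lower. A normal p from the authors' own test statistic called 698. Of 26 gene lists tested, 4 shifted up and 8 down.

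Cholesterol synthesis genes rose under Cnot1 shRNA. Of 19 tested, 14 were called higher and none lower, or 16 when adjusted over the list alone, with a median log2 fold change of 0.57 (adjusted p 0.000867 across random lists). Fdps and Dhcr7, enzymes of the pathway, rose from 9.31 to 17.5 and from 14.7 to 26.6 RPKM, by 0.91 and 0.85 on the log2 scale. Replication-dependent histone genes had a median of 0.40 (adjusted p 0.000867), with 8 of 19 called higher and 10 when adjusted over the list alone. Hist2h2ac rose by 1.15, Hist3h2a by 0.75 and Hist1h1e by 0.69. Interferon and double-stranded RNA response genes had a median of 0.41 (adjusted p 0.0303), with 6 of 16 called higher, among them Oas3 (1.61), Ifi35 (0.81) and Stat2 (0.77), and 8 when adjusted over the list alone. That call was lost at 5 RPKM or above (median 0.28, adjusted p 0.227). Cell cycle genes had a median of 0.15 (adjusted p 0.0231), with 5 higher, 1 lower and 30 of 36 uncalled, and 3 called when adjusted over the list alone. Ccnb2 rose by 0.63 and Ccnd3 by 0.62, while Tyms fell by 0.37. With random lists not matched on expression the adjusted p was 0.107. The called members of the last 2 lists were not in excess (Fisher's exact test, adjusted p 0.0914 for interferon and 0.905 for cell cycle genes).

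The 2-cell-like genes, expressed in a small fraction of embryonic stem cells, fell furthest under Cnot1 shRNA. Of 11 tested, 10 were called lower, likewise 10 when adjusted over the list alone, and the median was -2.24 (adjusted p 0.000867). Zscan4d fell from 5.92 to 1.20 RPKM and Gm8300 from 5.05 to 0.944. With a pseudocount of 1 the median was -1.30 (adjusted p 0.000867), and too few members reached 5 RPKM for a test there. Of 24 p53 targets, 14 were called lower and 3 higher, or 18 in all when adjusted over the list alone (median -0.40, adjusted p 0.000867). Mdm2, which encodes the ubiquitin ligase of p53, fell from 98.1 to 36.5 RPKM, Plk2 by 2.08 on the log2 scale, Pmaip1 by 1.33 and Phlda3 by 1.12. Cdkn1a, a p53 target and cell cycle inhibitor, read 27.4 and 34.9 RPKM and was not called. Imprinted genes had a median of -0.48 (adjusted p 0.000867), with 10 of 17 lower and 1 higher, and 11 when adjusted over the list alone. H19 fell by 1.57, Magel2 by 2.75 and Ndn by 0.80, while Phlda2 rose by 1.62.

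Immediate early and AU-rich-element genes moved both ways under Cnot1 shRNA, with 9 of 26 lower, 5 higher and a median of -0.33 (adjusted p 0.000867), and 16 called when adjusted over the list alone. Cyr61 fell by 2.05 on the log2 scale, Ctgf by 1.41 and Jun by 1.38, and Id2 fell from 11.3 to 4.01 RPKM. Heat shock genes had a median of -0.33 (adjusted p 0.0052), with 5 of 12 lower, including Hspa4l (-1.29) and Hspa1b (-1.04), and 5 when adjusted over the list alone. That call was lost at 5 RPKM or above (median -0.13, adjusted p 0.353). Small nuclear and cytoplasmic RNAs had a median of -0.35 (adjusted p 0.0303), with 6 of 12 lower and 6 when adjusted over the list alone. Scarna2, the most abundant entry of the table, fell by 0.47 and Snord17 by 1.02. At 5 RPKM or above the median was again -0.35, with an adjusted p of 0.0678. Among markers of other cell types, primitive endoderm genes had a median of -0.42 (adjusted p 0.0143, 5 of 8 lower, 7 when adjusted over the list alone), with Fst (-0.97) and Cited2 (-0.73) lowest. Neuroectoderm genes had a median of -0.52 (adjusted p 0.0303, 4 of 9 lower, 4 when adjusted over the list alone), led by Neurod1 (-1.88). Members of a list are not independent, so these p-values describe the list within these libraries.

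The pluripotency lists stayed near 0 as groups under Cnot1 shRNA. Naive genes had a median of 0.04 (adjusted p 0.785), with 5 of 26 higher and 3 lower, or 9 when adjusted over the list alone. Tdgf1, Fgf4 and Prdm14 rose by 0.84, 0.74 and 0.57, and Fbxo15 fell by 0.90. Pou5f1, Nanog and Sox2 read 172, 200 and 148 RPKM against 158, 163 and 130 in controls, none called. Of 11 primed genes 1 was called in either count, Dnmt3a (0.46), at a median of -0.01 (adjusted p 0.952). Described targets of the miR-290 and miR-302 families had a median of 0.18 (adjusted p 0.146), with 4 of 17 higher and 2 lower, and 7 when adjusted over the list alone. The Nodal antagonists Lefty2 and Lefty1 rose by 1.83 and 1.21, and the kinase gene Lats2 fell by 1.21. Of 16 microRNA pathway genes, 3 fell, including Lin28a (25.5 to 12.7 RPKM) and Ago3 (log2 fold change -0.69), at a median of -0.06 (adjusted p 0.574, 4 when adjusted over the list alone). Ago2 read 46.7 and 47.1 RPKM and Tnrc6a 38.0 and 40.7, neither called, and Ago1 was listed at 0.106 RPKM in controls and was not tested.

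Cnot7 shRNA was compared with the same controls to ask what targeting a catalytic subunit does. Cholesterol synthesis genes again rose, and 2-cell-like, germline, heat shock and imprinted genes fell. Large rises were those of Qprt (0.566 to 4.85 RPKM, log2 fold change 3.10 ± 0.97), B4galnt2 (2.80), C2 (2.71), Cd302 (2.63), Tmem211 (2.48), Selplg (2.48) and Amhr2 (2.41). The largest falls were Zscan4d (5.78 to 0.247 RPKM, log2 fold change -4.55 ± 1.07), Zscan4c (-4.12), Pmp22 (-3.39), Fam124a (-3.38), Hspa1b (-3.31), Rgs14 (-2.90), Ets1 (-2.81) and Zscan4f (-2.72). The fall of Pmp22 had an implied SE of 2.45, so its size is uncertain. Of 12059 tested genes, 1532 (12.7%) were called, 982 higher and 550 lower. Of 26 gene lists tested, 1 shifted up and 7 down. A normal p from the authors' own test statistic called 438, and the targeted gene itself was not among the calls.

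Of 19 cholesterol synthesis genes, 8 were called higher under Cnot7 shRNA and none lower, or 10 when adjusted over the list alone (median 0.47, adjusted p 0.00173). Msmo1, an enzyme of the pathway, rose by 0.79 on the log2 scale and Insig1, which restrains it, by 0.76. The 2-cell-like list fell to a median of -3.99 (adjusted p 0.00173), with 6 of 10 lower and 10 when adjusted over the list alone, and Tdpoz4 was listed at 0. With a pseudocount of 1 the median was -2.01 (adjusted p 0.00173), and again too few members reached 5 RPKM. Germline genes had a median of -1.23 (adjusted p 0.00173), with 6 of 13 lower and 7 when adjusted over the list alone. Slc25a31 fell by 2.14, the RNA helicase gene Ddx4 by 1.97, Stk31 by 1.78 and Mael by 1.77. The median was -0.72 with a pseudocount of 1 (adjusted p 0.00173), and the call was lost at 5 RPKM or above (median -0.14, adjusted p 0.649). Imprinted genes had a median of -0.36 (adjusted p 0.0052), with 6 of 17 lower, 1 higher and 9 when adjusted over the list alone. H19 fell by 2.35 and Magel2 by 2.24.

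Heat shock genes had a median of -0.44 under Cnot7 shRNA (adjusted p 0.0052), with 5 of 12 lower in either count, and Dnajb1 fell by 1.02 and Hsph1 by 0.95. At 5 RPKM or above the median was -0.26 (adjusted p 0.150). Of 24 p53 targets, 7 were lower and 2 higher, or 11 when adjusted over the list alone (median -0.23, adjusted p 0.0318), with Plk2 (-1.89), Mdm2 (-1.16) and Pmaip1 (-0.97) lowest. At 5 RPKM or above the median was again -0.23, with an adjusted p of 0.0943. Nuclear exosome and 3′ decay factors had a median of -0.26 (adjusted p 0.0199), with 2 of 23 lower in either count, C1d (-0.80) and Exosc2 (-0.55), and at 5 RPKM or above again a median of -0.26, with an adjusted p of 0.0521. Trophoblast genes had a median of -0.40 (adjusted p 0.0267) although 2 of the 3 called members rose, Tead4 (0.69) and Tfap2c (0.57), while Krt18 fell by 0.96, and 3 were called when adjusted over the list alone. That call was lost with a pseudocount of 1 (median -0.24, adjusted p 0.150) and at 5 RPKM or above (median -0.03, adjusted p 0.848). For exosome and for trophoblast genes the lower calls were not in excess (Fisher's exact test, adjusted p 0.686 for each).

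The medians of other lists did not pass the test under Cnot7 shRNA. Of 25 immediate early and AU-rich-element genes, 8 were called lower and 0 higher, or 11 when adjusted over the list alone, with Cyr61 (-2.31) and Ctgf (-1.18) furthest. The median was -0.21 (adjusted p 0.0566, and 0.0403 with a pseudocount of 1), while 1.14 lower calls were expected of a random list (Fisher's exact test, adjusted p 9.9e-05). Lefty2 and Lefty1 rose by 2.31 and 1.74 among 16 described miR-290 and miR-302 targets (3 higher, 1 lower, 4 when adjusted over the list alone), whose median was 0.11 (adjusted p 0.537). Of 26 naive genes, 4 were higher and 2 lower, or 7 when adjusted over the list alone, at a median of 0.04 (adjusted p 0.726). Of 19 histone genes none was called in either count (median -0.03, adjusted p 0.647).

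**Figure D2:**
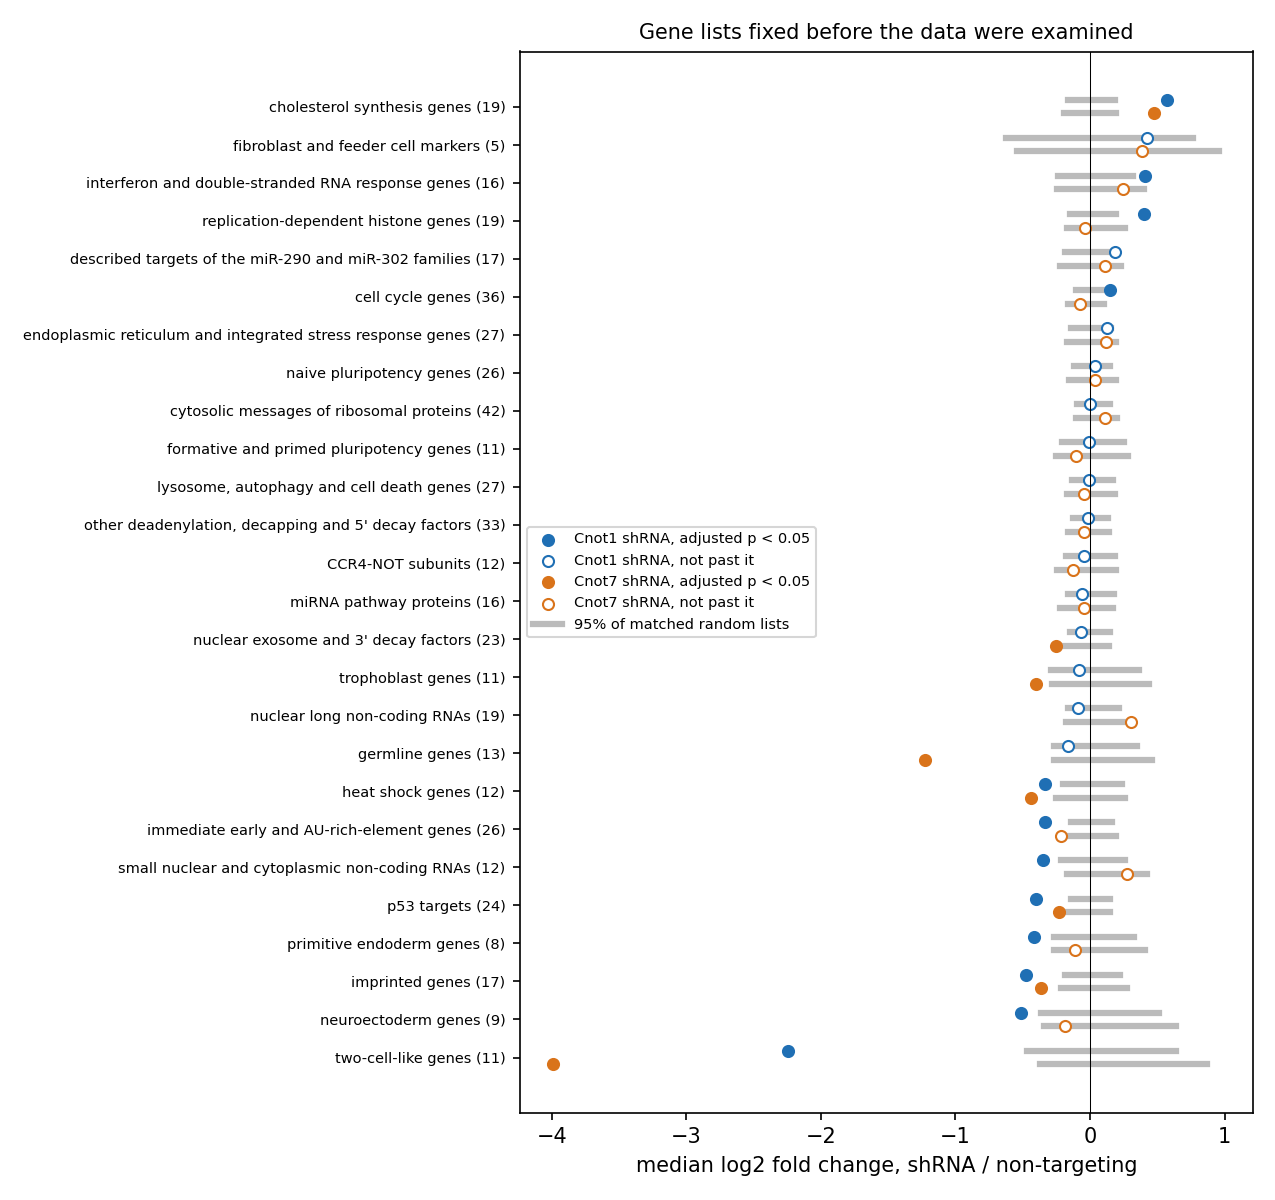
Points show the median log2 fold change of each gene list, shRNA over non-targeting, for Cnot1 shRNA (blue) and Cnot7 shRNA (orange), with the number of members tested under Cnot1 shRNA in parentheses. Filled points passed the adjusted p of 0.05, and grey bars span 95% of the matched random lists. The cholesterol synthesis median was 0.57 and 0.47, and the 2-cell-like median -2.24 and -3.99.

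Both comparisons were then set against each other, to ask whether the shRNAs acted on the same RNAs. Of 11919 genes tested in both, 822 were called higher under both and 401 lower under both, and 0 were called in opposite directions. Independent lists would share 122 and 46.0 genes. That value leaves out the shared controls, which raise the overlap with no effect at all. Qprt, Tmem211 and Lefty2 rose, and Ets1, Mdm2, Cyr61 and Zscan4c fell, under both shRNAs. Across 11836 genes with a finite fold in both, Pearson's r was 0.823 and Spearman's rho 0.787.

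Both comparisons use the same control libraries, which alone gives a correlation and an overlap. Over 11679 genes with implied errors up to 2, the observed r was 0.848. Simulated unchanged groups gave 0.435 with a share of 0.5 of the smaller error variance given to the controls, and 0.864 with all of it, so unchanged groups can reach the observed r. The observed covariance was 0.226, beside 0.0682 and 0.135 in the same simulations. Of these genes 820 were called higher and 398 lower under both. Lists of the same size from the unchanged groups shared 341 and 164 genes at a control share of 0.5, and 739 and 411 at the full share, so the overlap of the lower calls did not exceed that extreme. The controls could not be split, so part of the overlap and of the covariance may come from them. The test of the difference called 10 genes, 3 higher and 7 lower under Cnot1 than under Cnot7 shRNA, all of them microRNA genes, and 29 genes had an unadjusted p under 0.05. None of the 10 was called against controls, with the authors' deposited table giving p-values from 0.270 to 0.871, and with errors taken from those p-values 0 genes differed (199 at an unadjusted p under 0.05). The median error of a difference was 0.395, and a log2 difference of 1 was recovered for 13% of simulated genes, so most differences of that size would have been missed.

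**Figure D3:**
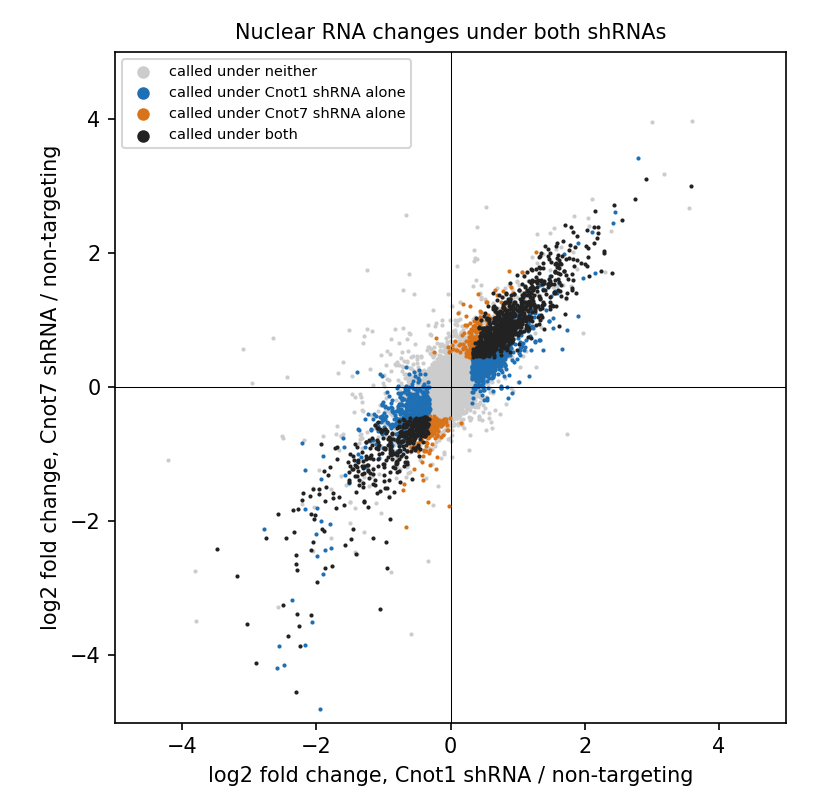
Each point is a gene tested in both comparisons, with the log2 fold change under Cnot1 shRNA on the x axis and under Cnot7 shRNA on the y axis, coloured by whether it was called under neither, under 1 shRNA alone or under both. Of 11836 genes, 5 lie outside the axes, which end at a log2 of 5 either way, and 0 of the 1223 genes called under both changed in opposite directions.

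Genes with a seed site of the miR-290 and miR-302 families in their 3′ UTR were compared with other genes, because CCR4-NOT acts in microRNA silencing. Genes with a site for the seed these families share did not move detectably apart from genes without one. Under Cnot1 shRNA the 2024 genes with a site had a median log2 fold change of 0.0045 and the 8930 without had 0.013. The difference exceeded that of permuted labels, matched on expression and UTR length, by 0.0082 (permutation adjusted p 0.547). Under Cnot7 shRNA the medians were 0.020 for 2013 genes and -0.0020 for 8798, an excess of 0.015 (permutation adjusted p 0.323). The only family past the threshold was miR-122, a liver microRNA included as a control, with an excess of 0.037 (permutation adjusted p 0.0229) under Cnot1 and 0.048 (permutation adjusted p 0.00444) under Cnot7 shRNA. The miR-17, let-7, miR-1 and miR-124 sites gave permutation adjusted p-values from 0.0745 to 0.981. Because a control family passed with a larger excess than the miR-290 and miR-302 seed, small excesses here cannot be read as microRNA effects. Cnot1 stood at 71.4% of controls under its own shRNA, and Cnot7 was not called under its own. The test therefore cannot decide what a stronger loss would do.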

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

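The tests of short transcripts, of nuclear enrichment, of length and GC content, of a state of the control cells and of fold sizes with errors from the authors' p were chosen only after the results were seen. Of 25 gene lists tested for a difference between the shRNAs, 8 differed, 5 higher and 3 lower under Cnot1 than under Cnot7 shRNA. The medians of the difference (Cnot1 minus Cnot7, log2) were 1.45 for the 2-cell-like genes, -0.18 for p53 targets, 0.21 for heat shock genes and 0.21 for cell cycle genes. They were -0.37 for nuclear long non-coding RNAs, -0.92 for small non-coding RNAs, 0.30 for histone genes and 0.25 for germline genes. Values of 2-cell-like genes were low under Cnot7 shRNA, with Zscan4d at 0.247 and Gm8300 at 0.378 RPKM. No list difference was repeated with a pseudocount or an RPKM filter, so the part played by low values was not tested. The 10 single genes that differed were Mir3082, Mir1839, Mir8110, Mir6945, Mir6914, Mir343, Mir7027, Mir6960, Mir6997 and Mir541, named after their values were seen. In 4 of them the Cnot7 log2 fold change equalled 0.299, the commonest ratio among genes with few reads.

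Small non-coding RNAs were lower, and histone messages higher, under Cnot1 than under Cnot7 shRNA. Unequal recovery of all short transcripts, acting alone, would move both the same way. The histone median was instead 0.30 (95% bootstrap interval over genes 0.19 to 0.45) and the small RNA median -0.92 (-1.06 to -0.54). Such intervals leave out any spread between cultures. Such recovery combined with another change stays open, since cell cycle genes also lay higher under Cnot1 than under Cnot7 shRNA (median difference 0.21). Unequal nuclear enrichment, acting alone, would move ribosomal-protein messages against the nuclear long non-coding RNAs. The ribosomal-protein median was instead -0.11 (-0.24 to -0.056), on the same side of 0 as that of the long non-coding RNAs at -0.37 (-0.50 to -0.24). It did not pass the test against matched lists (adjusted p 0.0722). Enrichment combined with another change, such as unequal recovery of short transcripts, also stays open. Of 18 nuclear long non-coding RNAs, 1 lay higher under Cnot1 than under Cnot7 shRNA. Unequal recovery of small structured RNAs stays open, since 123 of 158 other small RNA genes were also lower and their median was -0.53 (-0.74 to -0.40). An effect of the targeted subunits on these RNAs was not separately tested and also stays open.

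Genes called under either shRNA mostly moved the same way under both, against the same controls. The covariance exceeded the most that the implied errors allow the shared controls by 0.092 ± 0.0062 (bootstrap SE over genes). This argues against chance of the size of the implied errors as the whole cause. Those errors may be technical, so larger chance differences between control cultures are not excluded. Removing transcript length, GC content and expression took 3.02% of the covariance across 10704 genes. It stayed 0.099 ± 0.0061 above the limit for these genes, which was 0.117, against 0.135 for all genes used before. This argues against length and GC bias as the whole cause, under the same implied errors. Of genes called under either shRNA, 98.3% had the same sign under both, a share that decides nothing, since simulated unchanged groups gave 77.1% and, with all of the smaller error variance given to the controls, 99.03%. With 1 control group, a state of the non-targeting cells and a shared effect of both shRNAs cannot be told apart. Nor can an effect on CCR4-NOT be told from one unrelated to it, and Cnot7 was not called under its own shRNA.

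More genes were called under Cnot1 than under Cnot7 shRNA. A wider spread in the Cnot7 comparison may account for this. With the Cnot7 errors the Cnot1 folds gave 296 calls against 430 for the Cnot7 folds, a ratio of 0.688 ± 0.052 (bootstrap SE over genes). These calls used a normal p from the implied errors, which gave 677 for the Cnot1 folds with their own errors. Smaller errors of the Cnot1 folds (median 0.258 against 0.301) lower the ratio even for equal effects, so a ratio below 1 does not decide by itself. Larger folds under Cnot1 shRNA are argued against for these libraries. They needed a noise-corrected SD over 1.1 times that of the Cnot7 folds. It was 0.978 ± 0.022 times (0.968 ± 0.012 with errors from the authors' p). These bootstrap errors run over genes and leave out any spread between cultures. The lower relative depth of the Cnot7 libraries goes with the wider errors.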

How the results depend on the processing

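The normal p, the exclusion of shared loci and of small RNA genes, and the other errors of the difference were chosen after seeing the data. No paired analysis was possible because the deposited tables hold 1 value per group, and for the same reason DESeq2, per-library filters, the 4-library fit and leaving out each replicate were not run. Across the alternatives, 35 values for the main results stayed on their side of the threshold or within 1.5 times the count, and 10 moved. Under Cnot1 shRNA the 2566 calls became 1552 at an adjusted p below 0.01, 581 with at least a 2-fold change and 698 with a normal p from the test statistic. Under Cnot7 shRNA the 1532 calls became 812, 544 and 438 under the same settings. The first 2 are stricter by construction, and the cause of the last was not tested. At 5 RPKM or above, 7 of 23 lists shifted under Cnot1 shRNA and 2 of 23 under Cnot7 shRNA. Fewer genes and lists were tested there, and the cause of the lost calls was not tested. The 10 differing genes became 0 with errors from the authors' p and 0 without small RNA genes. Without the shared control part of the error 12 genes differed, among them Crispld2, which lay 1.38 higher under Cnot1 shRNA (adjusted p 0.016, against 0.676 otherwise). No called direction reversed. The correlation of the folds ranged from 0.783 to 0.854. The excess of the miR-290 seed reached at most 0.041, with permutation adjusted p-values from 0.110 to 0.547. Centring ended the calls of Rpl8 under Cnot1 shRNA and of Tgfbr2 and Trib3 under Cnot7 shRNA. With random lists matched on the control values alone, adjusted p-values became 0.0794 for interferon genes and 0.109 for small non-coding RNAs under Cnot1 shRNA, and 0.0924 for p53 targets under Cnot7 shRNA. Unknown absolute depth limits what low genes can show.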

Other observations

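Fatty acid genes rose along with those of cholesterol synthesis under both shRNAs. Scd1 and Scd2, which desaturate fatty acids, rose from 10.3 to 47.0 and from 62.4 to 283.7 RPKM under Cnot1 shRNA, and by 2.30 and 2.22 on the log2 scale under Cnot7 shRNA. Mid1ip1, an activator of acetyl-CoA carboxylase, rose by 2.05 and 1.93. Outside these, the desaturases Fads2 and Fads1 rose by 1.36 and 1.22 under Cnot1 and by 1.05 and 1.11 under Cnot7 shRNA, and Srebf1, which encodes a transcription factor of lipid synthesis, by 0.82 and 0.90. The genes named here were picked for the size of their changes.

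Of 27 lysosome, autophagy and cell death genes, 7 were called higher and 4 lower under Cnot1 shRNA, and 5 higher and 0 lower under Cnot7 shRNA, and the list passed neither test (Fisher's exact test, adjusted p 0.375 and 0.553 for higher calls). Lamp2, a lysosomal membrane protein, rose by 0.85 under both, the protease gene Ctsl by 0.59 and 0.69, and Ctsb by 0.57 and 0.61. Those lower under Cnot1 shRNA, named after their values were seen, were Bcl2l1 (-0.51), Becn1 (-0.50), Atg5 (-0.48) and Atg12 (-0.42). Of the stress response genes, Vldlr rose by 1.17 and 1.40, Nupr1 by 1.13 and 0.93, and Trib3 by 0.55 and 0.53. The nuclear RNA Neat1 rose by 0.50 and 0.84. Malat1 read 2919 RPKM under Cnot1 shRNA against 2567 in controls and 3795 under Cnot7 shRNA against 2508 (log2 fold changes 0.19 and 0.60), and neither was called. Thy1, a surface marker of fibroblasts, rose from 1.18 to 5.77 RPKM under Cnot1 shRNA and by 2.02 under Cnot7 shRNA. Of 5 tested fibroblast markers, 3 were called under Cnot1 shRNA, Thy1 and Col5a1 (0.42) higher and Twist1 (-1.08) lower, and Thy1 alone under Cnot7 shRNA, and the list's median passed the test under neither.

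The medians of the lists not yet described did not pass the test. Under Cnot1 and Cnot7 shRNA these were -0.05 and -0.13 for CCR4-NOT subunits, -0.02 and -0.04 for other deadenylation and decapping factors, -0.01 and -0.05 for lysosome and cell death genes, and 0.13 and 0.12 for stress response genes. They were 0.00062 and 0.11 for ribosomal-protein messages, -0.09 and 0.30 for nuclear long non-coding RNAs (adjusted p 0.0334 under Cnot7 shRNA with lists matched on the controls alone) and 0.42 and 0.38 for fibroblast markers. Interferon genes, small non-coding RNAs, neuroectoderm, primitive endoderm, cell cycle and primed genes under Cnot7 shRNA had medians of 0.24, 0.28, -0.18, -0.11, -0.08 and -0.10. Under Cnot1 shRNA the medians were -0.08 for trophoblast genes, -0.16 for germline genes and -0.06 for exosome factors. Of the 13 germline genes 5 were called lower and 1 higher, where 1.09 lower calls were expected (Fisher's exact test, adjusted p 0.0098). MicroRNA pathway genes under Cnot7 shRNA had a median of -0.04. Mesoderm genes had fewer than 5 tested members, of which Snai1 fell by 0.92 and 1.38, and mitochondrially encoded genes were not analysed here.

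Both lists below were written after some of their members had been seen, and those members were left out of the tests. For the fatty acid list these were Scd1, Scd2 and Mid1ip1. A hypothesis of higher SREBP-driven fatty acid synthesis was tested on the 13 remaining members. Their median was 0.57 under Cnot1 and 0.46 under Cnot7 shRNA, at percentiles 99.99 and 99.98 of matched random lists, which is consistent with the hypothesis, and 10 and 5 members were called higher with 0 lower. Without Fads1, Fads2 and Srebf1 too, a test added later, the 10 members left had medians of 0.39 and 0.34, at percentiles 99.7 and 98.97, with 7 and 2 called higher. The test ranked RNA changes only. It measured neither SREBP activity nor fatty acid synthesis, so it does not show what raised these genes. A state of the control cells may give the same result. Under Cnot7 shRNA the synthesis genes Fasn (0.14), Acly (0.22) and Acaca (0.46), all called higher under Cnot1 shRNA, were not called. A hypothesis of lower YAP and TEAD activity came from the falls of Cyr61, Ctgf and Lats2. The 14 other members had medians of -0.02 and -0.08, at percentiles 38.4 and 20.04, so the low median that the hypothesis predicted was not seen. This argues against a fall of these 14 members as a group, and leaves out the seen members, which fell. Members were called both ways, so the median does not speak for each of them. It does not decide on YAP and TEAD activity. Amotl2 fell by 1.24 and 1.16 and Ptpn14 by 1.52 and 1.12, and Axl rose by 0.75 and 0.94.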
